A study of Mus musculus with 4 samples.

How the data were processed

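Total RNA of cultured mouse IMS/N stellate cells was measured on 4 one-colour arrays, 1 for each of the conditions control, PA (palmitic acid), ADSC medium (medium from cultured adipose tissue-derived stem cells), and PA and ADSC medium. RNA was extracted with ISOSPIN Cell & Tissue RNA, then amplified and given a Cy3 label by Agilent's Quick Amp kit, per the labels' protocols. The dose and time of PA, and what the control received in place of it, are not given in the sources used here. The arrays carried Agilent design 014868, annotated on mouse genome build mm9, and were read with Agilent Feature Extraction 12.1.1.1 under protocol GE1_105_Dec08, per the file headers. The deposited values used are the processed signal of each spot, an intensity from which the authors' scanner software had subtracted the background and removed spatial and multiplicative trends within each array, per the file headers. These intensities were not normalized between arrays, per the file headers. The authors then applied quantile normalization, per the series' design notes, and used R 3.5.1, per the submitters' processing notes. They also deposited a pair of lists of probe names without values, of 1580 and 920 probes, whose selection threshold is not given in the sources used here. All names in both lists were checked against the array and belong to probes that are not controls.

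Control spots were left out, and spots with an outlier flag of the scanner software were dropped (82 to 104 on an array). Values were taken to log2, spots of the same probe were averaged, and the 4 arrays were quantile-normalized together with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8). Of 41174 probes 41146 had a value on every array, and 28 were left out. A probe counted as well above background when the scanner software's flag said so on more than 50% of its spots. Gene symbols came from the reference gene table for 28680 probes matched by RefSeq accession, which changed 635 of the array's names; 12466 probes kept the name the array gives. Each of the 26793 gene names was represented by its probe with the highest mean over the 4 arrays, and 9187 names had several probes. Probe positions are those of the files, on mm9. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

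With 1 array per group no test between conditions was run and no p-value was computed. An additive fit of PA and ADSC medium to the 4 arrays would leave 1 residual degree of freedom, and that residual is the difference between the effects without and with the other treatment, which the text describes; it was not used as error. A gene entered a comparison when it was well above background on at least 1 of its 2 arrays. Where it was well above background on only 1, the dimmer value was replaced by the higher of its own value and the lowest level well above background on that array, and the difference is a lower bound, written "at least". These lowest levels were 2.43 (control), 2.07 (PA), 2.30 (ADSC medium) and 2.11 (PA and ADSC medium). Genes at least 2-fold higher or lower were counted in 5 comparisons: PA, ADSC medium, and PA and ADSC medium each against control, PA and ADSC medium against PA, and PA and ADSC medium against ADSC medium. The spread of the measurement came from 245 probes printed on 10 spots per array. From that spread, 100 sets of unchanged arrays were simulated with fixed seeds, to give the counts that spot noise alone produces and the overlap of comparisons that share the PA array. The noise of all replicate spots was used; the noise of those well above background only was added after the first simulated counts were seen. Both leave out the variation between cultures.

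The gene lists were 29 in number, with 645 entries, of which 642 were found on the array and 589 were well above background on at least 1 array. They were stellate activation and contractile, fibrillar collagen and matrix, quiescent stellate, matrix metalloproteinases and inhibitors, TGF-beta targets, unfolded protein response, ATF4 and amino acid stress, PPAR targets and fatty acid oxidation, cholesterol synthesis, fatty acid synthesis and desaturation, inflammatory NF-kB targets, and interferon response. Further lists were cell cycle, p53 targets, NRF2 and oxidative stress, hypoxia and glycolysis, heat shock, autophagy and lysosome, immediate early, oxidative phosphorylation, ribosomal proteins, growth factors and receptors, and housekeeping. Marker lists covered adipose stromal cells or adipocytes, hepatocytes, macrophages, endothelial cells, biliary or epithelial cells, and portal fibroblasts or mesothelial cells. For each list the median difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level so that each member was matched on level. A list stood apart when its median lay outside the middle 95% of these. The groups, comparisons, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

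Genes were named by a fixed rule. For PA against control, PA and ADSC medium against PA, and ADSC medium against control, these were the 10 highest and the 10 lowest among genes at least 2-fold different under the main, 75th percentile and normexp settings. Their probe had to be well above background on both arrays, not saturated, and in the upper 50% of the detected levels on its brighter array; symbols that are accessions or clone names were passed over. Added to these were up to 4 members of each list with the largest difference measured on both arrays, and 25 genes of stellate activation, matrix, inflammation and lipid response named whatever their values. Genes named outside the rule are marked as such, and some genes the rule takes are not reported here.

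The alternatives changed 1 choice at a time. They were a shift of each array to its 75th percentile in place of quantile normalization, a normexp background (offset 50) followed by quantile normalization, genes well above background on both arrays only, no filter on dim probes, the mean of a gene's detected probes, and a threshold of 1.5-fold. Detected probes were those well above background on at least 1 of the 4 arrays. Their mean can therefore take in a probe near background on the arrays compared, as for Cck and Il1rn. For genes higher with PA, selection on one probe and readout on a second probe of the gene was used as well. The same readout and alternatives for genes lower with PA and higher again were added after that count was seen. Correlations across genes used genes well above background on all 4 arrays, with 200 bootstrap resamples of genes for their spread. Shares carry 95% Wilson intervals, which cover counting only.

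The computation was tested on simulated data for PA against control, with 17607 genes of which 200 were changed, 50 at each of the sizes 1.5-, 3-, 4- and 8-fold, under the noise of all replicate spots. Past 2-fold in the right direction were 0 of 50 genes changed 1.5-fold and all 50 at each of 3-, 4- and 8-fold, along with 61 of 17407 unchanged genes. Of 200 lists of 25 unchanged genes, 12 (6.0%) stood apart. With the noise of spots well above background, 49 of 50 genes changed 3-fold were found, and 15 unchanged genes passed.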

Results

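RNA was measured in IMS/N cells, a line of hepatic stellate cells from normal mouse liver that was immortalized with SV40. Stellate cells are the liver cells that become contractile, matrix-producing myofibroblasts when activated. The cultures were grown with or without palmitic acid (PA), a saturated fatty acid, and with or without medium from cultured adipose tissue-derived stem cells (ADSCs) of C57BL/6J inguinal fat. The series title asks whether ADSCs restore stellate cells activated by PA. Total RNA of the 4 conditions (control, PA, ADSC medium, and PA and ADSC medium) was hybridized to 1 one-colour Agilent array each. No condition has a replicate, so each difference reported here describes 2 arrays and carries no p-value. The same contrast on the other 2 arrays is given for PA and for ADSC medium.

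Each array held 45018 spots, of which 43379 were not controls, and no spot was saturated. The share of probes well above background was 67.5% on the control array, 70.0% on the PA array, 68.5% on the ADSC medium array and 69.4% on the PA and ADSC medium array. In the same order, the 75th percentile of the processed intensity was 476, 602, 473 and 518. All 4 arrays sat on 1 slide and were read in 1 scan. Of 26793 gene names, 18930 were well above background on at least 1 array and 17355 on all 4. Levels are quantile-normalized log2 intensities, and differences are on the log2 scale unless a fold is given. For probes well above background, the SD of the difference between 2 single spots was 0.067 at levels of 9 to 11 and 0.408 under a level of 3. It covers the measurement on the arrays but not the variation between cultures. Spots not well above background, which the main simulation also draws on, are left out of this SD. The number of arrays limits the precision.

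PA was compared with control to ask which genes differed when the fatty acid was given. Interferon response genes were higher with PA as a group. All 34 members of the interferon list with a value were higher, 31 of them by at least 1.5-fold and 28 by at least 2-fold, and their median difference was 2.02, a 4.07-fold higher level. Mx2 (chromosome 16, 97782327 to 97782386, mm9) was 10.7-fold higher, at a level of 12.45 against 9.04, and Rsad2 10.3-fold; both encode antiviral effectors. Ifi44 was 9.71-fold higher, Ifit3 9.31-fold, and Zbp1, a sensor of nucleic acids, 9.39-fold. Cxcl10, a chemokine that attracts T cells, was 6.61-fold higher and reached a level of 14.64. Ifit3b and the interferon-inducible GTPase genes Iigp1 and Tgtp1, which no fixed list held, were 9.54-fold, 7.84-fold and 6.58-fold higher, although another probe of Tgtp1 showed a difference of only 0.88.

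Some inflammatory genes were also higher with PA. Ccl4, a chemokine (chromosome 11, 83478052 to 83478111), was 18.8-fold higher, at a level of 7.71 against 3.48, but its difference of 4.23 was 1.97 with the normexp background. Of the 25 members of the NF-kB target list with a value, 6 were at least 1.5-fold higher, 1 was as much lower and 18 were neither, with a median of 0.31 that was 0.13 with normexp. Among them, Il6 (chromosome 5, 30346362 to 30346421) was 4.78-fold higher (2.26, or 1.60 with normexp), Ccl5 differed by 2.06 and Saa3, an acute-phase gene, by 1.08. Ccl2 (0.41, or 0.27 with the 75th percentile scaling) and Cxcl1 (0.56) were higher by less than 1.5-fold. Of 29 targets of ATF4, the transcription factor of the amino acid stress response, 24 were higher by any amount and 3 by at least 1.5-fold (median 0.29), with Atf3 at 0.88, Cth at 0.70, Gdf15 at 0.61 and Trib3 at 0.28. The 21 p53 targets had a median of 0.32, with 18 higher by any amount but only 1 by at least 1.5-fold, 1 as much lower and 19 neither. Pmaip1, which encodes the death-promoting protein Noxa, differed by 1.48, and Sesn1 by -0.78.

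Of the genes that respond to fatty acids, Angptl4, which encodes an inhibitor of lipoprotein lipase, was 2.53-fold higher with PA. Acot2 (0.98) and Ehhadh (0.81) were also higher by at least 1.5-fold, whereas the 25 members of the PPAR target list had a median of 0.001, which turned to -0.018 with the 75th percentile scaling. Pdk4 (-0.02), Cpt1a (0.17, or 0.11 with the mean of detected probes) and Plin2 (0.27, or 0.14 with the 75th percentile scaling) differed little. The median of the 22 unfolded protein response genes was 0.05 and turned to -0.03 with the 75th percentile scaling. None of the 22 differed by 1.5-fold. Ddit3 was at 0.50, and Hspa5, which encodes the chaperone BiP, was at 0.15 and turned to -0.007 with that scaling.

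All 24 cholesterol synthesis genes were lower with PA by any amount, 4 of them by at least 1.5-fold, with a median of -0.40. Mvk (mevalonate kinase) was at -0.88, Acat2 at -0.76 and Idi1 at -0.69. Of 22 genes of fatty acid synthesis and desaturation, 16 were lower by any amount and 1 by at least 1.5-fold (median -0.20), with Elovl6 at -0.63, Acss2 at -0.57 and Scd1 at -0.20. Of 25 NRF2 and oxidative stress genes, 22 were lower by any amount and 6 by at least 1.5-fold (median -0.20, or -0.31 with the 75th percentile scaling), including Gsta4 at -0.98, the glutathione synthesis gene Gclm at -0.79 and Nqo1 at -0.76. Hmox1 was at -0.22.

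Of 23 fibrillar collagen and matrix genes, 20 were lower with PA by any amount but only Col3a1 (-0.84) by at least 1.5-fold, Tnc was as much higher (0.70), 21 were neither, and the median was -0.19. Col1a1 differed by -0.16 (-0.31 with the 75th percentile scaling) and Col1a2 by -0.37, or by -0.81 with the mean of detected probes. The 23 stellate activation and contractile genes had a median of -0.10, with 2 higher by at least 1.5-fold, 1 lower and 20 neither. Pdgfrb, the receptor for platelet-derived growth factor, was 1.91-fold lower, and Des was 1.84-fold higher but at low levels of 3.63 and 4.51, and at 0.21 with normexp. Acta2, which encodes alpha-smooth muscle actin, differed by -0.20 (-0.62 with the mean of detected probes), Tgfb1 by 0.08 and Ccn2 by 0.28, or by 0.13 with the 75th percentile scaling. Timp1 (0.13) and Vim (0.03) turned to -0.004 and -0.19 with the 75th percentile scaling. The 20 TGF-beta targets had a median of -0.12 (-0.07 with normexp), with only Tgfbi (-0.65) lower by at least 1.5-fold. The matrix metalloproteinase gene Mmp3 (chromosome 9, 7455751 to 7455810) was 7.77-fold lower (-2.96, or -2.18 with normexp), Mmp13 was 2.21-fold higher, and the 18 members of its list with a value had a median of -0.08.

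Among the genes lower with PA outside the lists, Ranbp3l was 5.97-fold lower (-2.58, or -1.74 with normexp), and the proteoglycan genes Omd and Ogn 3.21-fold and 3.03-fold. Synpo was 2.92-fold lower, with a second probe at -0.32. Slco4a1 was 2.65-fold lower, Dmpk 2.32-fold, Tmem119 2.23-fold and Mrgprf 2.18-fold.

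In all, 199 genes were at least 2-fold higher with PA and 109 at least 2-fold lower, of 18209 compared; 32 and 23 of these are lower bounds, since the gene was not well above background on the dimmer array. In 100 simulations of unchanged arrays with the noise of replicate spots, a mean of 28.5 genes passed as higher and 29.2 as lower, against 167 and 86 measured on both arrays. With the normexp background the counts were 106 and 11, without the filter on dim probes 664 and 552, and at 1.5-fold the balance turned, with 532 higher and 596 lower. The medians of 13 of the 29 gene lists lay outside the middle 95% of 10000 random lists of the same size matched on level. Lists of unrelated genes would give 1.45. Members of a list can vary together between cultures, and some lists share genes, so 1.45 is not the number expected between 2 unchanged cultures. The count of 13 is a description of these arrays. The interferon, NF-kB, ATF4 and p53 medians lay at percentile 100 and the cholesterol median at 0.

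**Figure D1:**
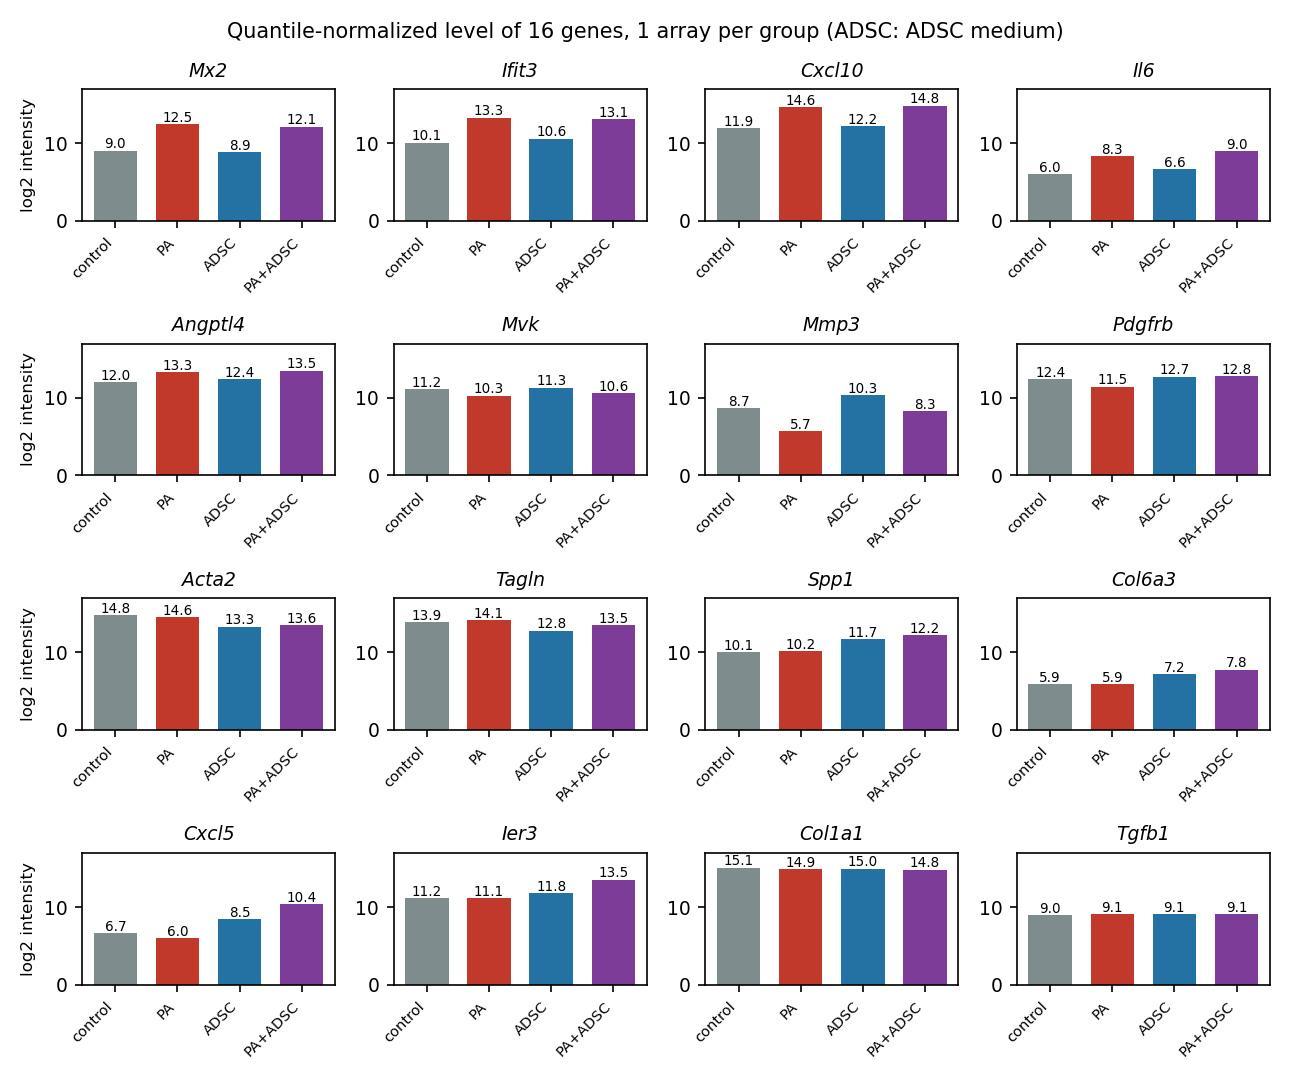
Quantile-normalized log2 intensity (vertical axis, from 0) of 16 genes on the 4 arrays, 1 bar per array, with the level above each bar. Mx2 stood at 12.45 and 12.13 on the arrays with PA against 9.04 and 8.88 on those without it, and Acta2 at 13.35 and 13.56 on the arrays with ADSC medium against 14.78 and 14.58 without it.

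The PA and ADSC medium array was compared with the PA array to ask what the medium did to cells given PA. Large differences were mostly in genes higher with the medium, 63 by at least 4-fold against 2 lower. Ranbp3l (chromosome 15, 8996153 to 8996212) was 29.2-fold higher, Cck, which encodes the peptide cholecystokinin, 25.4-fold, and Cxcl5, a chemokine that attracts neutrophils (chromosome 5, 91190205 to 91190264), 21.6-fold. Slco4a1 was 12.9-fold higher, Lrrn3 7.02-fold, Lce1f 6.24-fold, the nuclear receptor gene Nr4a2 6.17-fold and Mmp3 5.91-fold. Lce1g was 5.84-fold higher, although its second probe was at 0.57. Several of these sizes depend on the processing: Cck was at 4.66 but 2.52 with the mean of detected probes, and with normexp Ranbp3l was at 3.84 in place of 4.87, Cxcl5 at 3.64 in place of 4.44, Mmp3 at 1.84 in place of 2.56 and Lce1f at 1.94 in place of 2.64.

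Some inflammatory and immediate early genes were higher with ADSC medium in the presence of PA. Of 25 NF-kB targets, 8 were at least 1.5-fold higher, none as much lower and 17 neither. Their median of 0.11 was 0.04 with normexp and 0.19 with the mean of detected probes. Cxcl1 was 5.81-fold higher, Ptgs2, the cyclooxygenase gene, was at 1.93, Il33 at 1.79, Ccl2 at 0.96 and Il6 at 0.71. Of 20 immediate early genes, 8 were at least 1.5-fold higher, 4 of them at least 2-fold, and none as much lower, though 3 were lower by any amount. The median was 0.43 (0.28 with normexp), with Ier3 at 2.40, Nr4a1 at 1.72 and Egr2 at 1.21. The hypoxia and glycolysis list had a median of 0.33, with 25 of 26 genes higher by any amount and Adm (1.05), Slc2a1 (0.67) and Hk1 (0.62) among the 4 higher by at least 1.5-fold.

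Some matrix genes were higher with the medium in the presence of PA. Of 23 fibrillar collagen and matrix genes, 6 were at least 1.5-fold higher, 1 as much lower and 16 neither (median 0.31), with the collagen VI genes Col6a3 and Col6a1 at 1.88 and 0.79, decorin (Dcn) at 0.72 and Col3a1 at 0.65. Col1a1 (-0.11) and Col1a2 (0.20) differed little, though with the mean of detected probes they were at -0.21 and 0.42. Of 19 metalloproteinases and inhibitors, 6 were at least 1.5-fold higher and 2 as much lower (median 0.26), including Mmp13 at 1.68 and the plasminogen activator gene Plat at 1.21, while Mmp2 was at 0.47 (0.31 with normexp) and Timp1 at 0.30. The stellate list was split, with 4 genes at least 1.5-fold higher, 5 as much lower and a median of -0.07. Spp1 (osteopontin) was 4.11-fold and Pdgfrb 2.51-fold higher, and Des was 2.20-fold and Acta2 2.02-fold lower. Des was at -1.14 but -0.25 with normexp, and Acta2 at -1.02 but -0.56 with the mean of detected probes. Tgfb1 (-0.01) and Ccn2 (-0.26, or -0.15 with the 75th percentile scaling) differed by less than 1.5-fold, and the TGF-beta targets had a median of 0.001.

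Genes lower with the medium were fewer. Only 4 passed the rule for named genes. These were Klhl30 at 2.80-fold lower, Crct1 at 2.51-fold, Nup210 at 2.40-fold and the glutamate transporter gene Slc1a6 at 2.11-fold. Interferon response genes stood slightly lower, 29 of 34 by any amount and 2 by at least 1.5-fold (median -0.26), with the antigen presentation genes Tap1 at -0.91 and Psmb9 at -0.71. Cholesterol synthesis genes had a median of 0.14 (0.17 with the 75th percentile scaling, as had the housekeeping genes), with 20 of 24 higher by any amount and none by 1.5-fold. NRF2 and oxidative stress genes also had a median of 0.14 (0.24 with the 75th percentile scaling), with Gsta1 at 1.04 and Gsta4 at 0.73.

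With PA present, 328 genes were at least 2-fold higher with ADSC medium and 95 at least 2-fold lower, of 18751 compared. Measured on both arrays were 277 and 75 of these, against simulated means of 38.9 and 38.7. The count of lower genes was 60 with the 75th percentile scaling and 4 with the normexp background, which left 96 higher. Without the filter on dim probes the counts were 742 and 479. Of the 29 lists, 14 stood apart from random lists of the same kind.

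ADSC medium was compared with control to ask what the medium did without PA. The sample titles do not say whether cultures without ADSC medium received the same medium without ADSC products. Effects of the base medium and of ADSC products therefore cannot be told apart, here or in the presence of PA. Several contractile genes were lower. Acta2 (chromosome 19, 34316060 to 34316119) was 2.70-fold lower, with 3 other probes between -1.16 and -0.33 and the mean of detected probes at -0.75, and its paralogs Acta1 and Actc1 were 2.85-fold and 2.17-fold lower. The myosin light chain gene Myl9 was 2.40-fold lower, the calponin gene Cnn1 2.28-fold and Tagln 2.15-fold, while Actg2 was at -0.36. In the stellate list 4 of 22 genes were at least 1.5-fold lower, 2 as much higher and 16 neither, with a median of -0.11 (-0.05 with normexp). The TGF-beta target list, with a median of -0.17, held 14 genes lower by any amount, among them Ltbp2 (-0.63) and Pmepa1 (-0.43), but Tgfbi was higher (0.76). Klhl30 was 2.92-fold and Slc1a6 2.01-fold lower.

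Cck (chromosome 9, 121399031 to 121399090) was 6.20-fold higher with ADSC medium alone (2.63, or 1.49 with the mean of detected probes), Cxcl5 3.48-fold, Mmp3 3.15-fold and Spp1 (chromosome 5, 104869788 to 104869847) 3.12-fold. The prolactin family genes Prl2c5 and Prl2c3 were 2.93-fold and 2.80-fold higher, Il1rl1, the receptor for interleukin-33, 2.82-fold, and Il1rn, the interleukin-1 receptor antagonist, 2.60-fold (1.38, or 1.98 with the mean of detected probes). Ranbp3l was 2.65-fold and Tmem45a 2.61-fold higher. Of 23 NF-kB targets with a value, 4 were at least 1.5-fold higher and 1 as much lower (median 0.22, or 0.11 with normexp), with Cxcl1 2.15-fold higher, Il33 at 0.98 and Saa3 at -0.85. Mmp19 (1.30), Mmp2 (1.09), Col6a3 (1.27) and Dcn (0.76) were higher among the matrix genes, whose list had a median of 0.07, and Col1a1 was at -0.13 (-0.20 with the mean of detected probes).

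Lipid synthesis and glycolysis lists were higher by small amounts with ADSC medium alone. Cholesterol synthesis genes had a median of 0.19, with 23 of 24 higher by any amount and none by 1.5-fold. Fatty acid synthesis genes had a median of 0.17, led by Acsl3 at 0.49 and Elovl5 at 0.45. Hypoxia and glycolysis genes had a median of 0.26, with 24 of 26 higher by any amount and Pdk1 at 1.14. ATF4 targets had a median of -0.12 with 25 of 29 lower by any amount, and interferon response genes a median of -0.06.

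Without PA, 97 genes were at least 2-fold higher with ADSC medium and 22 at least 2-fold lower, of 18198 compared. Measured on both arrays were 80 and 18 of these. The simulated means were 25.5 higher and 25.8 lower, so with the noise of all replicate spots the number of lower genes was not above that of unchanged arrays. With the noise of spots well above background, a choice made after seeing the data, the simulated mean of lower genes was 7.45 (2 to 17), under the 18 measured. The choice of noise thus decides whether the count of lower genes exceeds that of unchanged arrays. The noise of all replicate spots also draws on spots not well above background, whereas the 18 were well above background on both arrays. With the normexp background the counts were 19 and 8, and without the filter 623 and 492. Of the 29 lists, 17 stood apart from random lists of the same kind.

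The PA and ADSC medium array was set against the ADSC medium array to ask whether the response to PA differed when the medium was present. The interferon list was again higher with PA, with all 34 genes higher, 25 of them by at least 2-fold, and a median of 1.97. Mx2 was 9.55-fold, Rsad2 5.35-fold, Cxcl10 6.05-fold and Ccl4 14.9-fold higher, the last from a low level of 4.99. Il6 was 5.22-fold higher and Angptl4 2.18-fold. Of 25 NF-kB targets, 12 were at least 1.5-fold higher and 1 as much lower (median 0.49), with Cxcl5 3.85-fold and Ccl2 2.23-fold higher. All 24 cholesterol genes were lower, 8 of them by at least 1.5-fold, with a median of -0.49, and Mmp3 was 4.14-fold lower. Pdgfrb, 1.91-fold lower with PA alone, differed by 0.04, and Ranbp3l was 1.85-fold higher with PA in the medium against 5.97-fold lower without it.

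In this comparison 233 genes were at least 2-fold higher and 88 at least 2-fold lower, of 18465, and 13 of the 29 lists stood apart. Normexp gave 105 and 9, and no filter 659 and 526. Across the 17355 genes measured on all 4 arrays, the PA difference without the medium correlated with that in the medium with Pearson's r of 0.533 and Spearman's rho of 0.373. These differences share no array, and simulated unchanged arrays gave a mean r of 0.002. The ADSC medium difference without PA correlated with that in the presence of PA with r of 0.494 and rho of 0.375. Genes are not independent replicates, so no p-value is given for either of these 2 relations. In a count chosen after the data were seen, of 165 of these genes at least 2-fold higher with PA without the medium, 164 were higher and 124 at least 2-fold higher with PA in it. Of 86 at least 2-fold lower, 66 were lower and 18 at least 2-fold lower. Of 68 genes at least 2-fold higher with ADSC medium without PA, 65 were higher with it in the presence of PA, and all 16 at least 2-fold lower were lower. Among all 17355 genes, 47.0% were higher and 52.9% lower with PA in the medium. With ADSC medium in the presence of PA, 46.3% were higher and 53.5% lower. The ADSC medium difference was at least 2-fold higher in the presence of PA than without it for 155 genes and at least 2-fold lower for 53. Each such value holds the noise of 4 arrays, and no simulated count is given for it, so part of both counts may be noise. Ranbp3l (3.46), Cxcl5 (2.64), Slco4a1 (2.43) and Cck (2.03) were among the 155, and Acta2 differed by 0.41. For Cck and Acta2 the ADSC medium differences without and with PA were both smaller in size with the mean of detected probes, as given above.

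**Figure D2:**
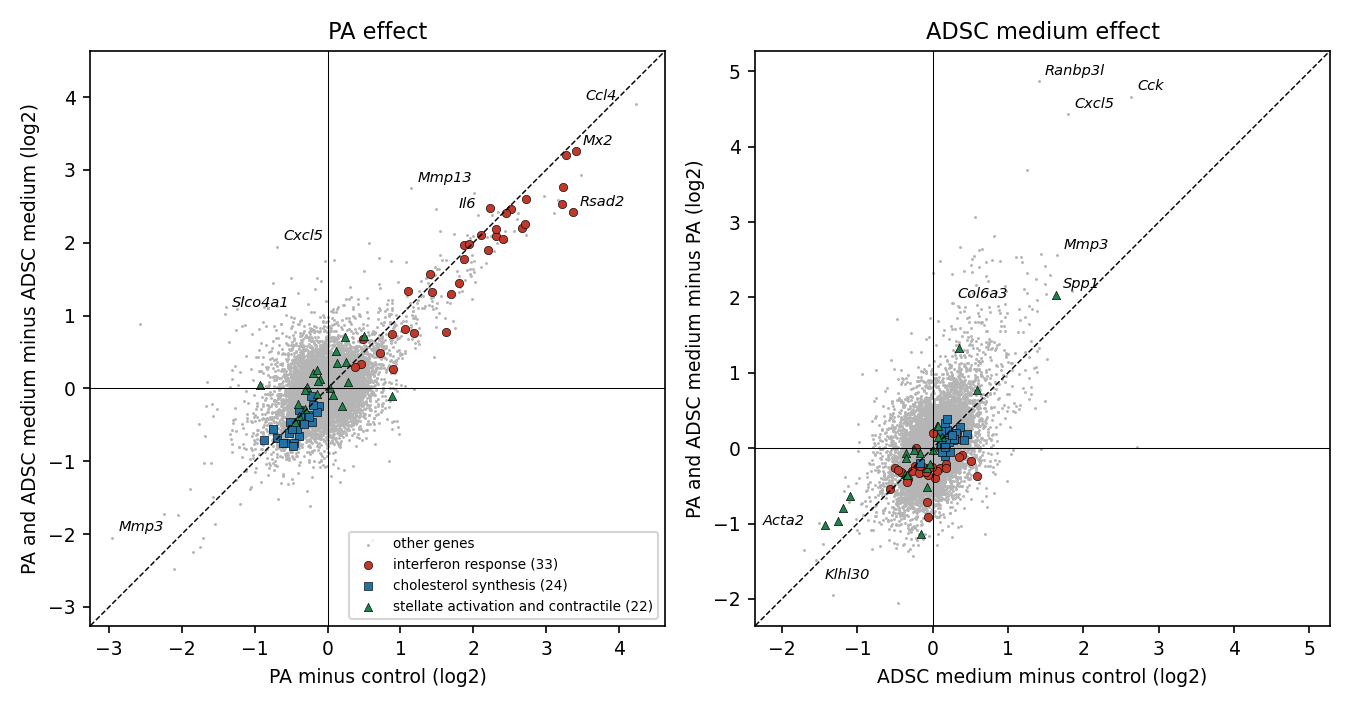
Log2 differences of genes well above background on all 4 arrays, 1 point per gene: PA without ADSC medium (left, horizontal) against PA with it (left, vertical), and ADSC medium without PA (right, horizontal) against with PA (right, vertical), with the dashed line marking equal differences. Interferon genes lie along or below the line on the left, with Mx2 at 3.42 and 3.26 and Rsad2 at 3.37 and 2.42. Ranbp3l, Cck and Cxcl5 lie well above the line on the right.

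The series asks which genes higher with PA were lower again with ADSC medium. Of 199 genes at least 2-fold higher with PA, 10 were at least 2-fold lower with PA and ADSC medium than with PA. Named after their values were seen, the 4 measured on each array concerned were Cdsn (1.25 with PA against control, then -1.22), Dennd2d (1.07, then -1.34), Sox13 (1.19, then -1.13) and Zfp352 (1.01, then -1.19). Zfp352 stood at low levels of 3.03 (control), 4.035 (PA) and 2.85 (PA and ADSC medium). Tnfsf10, which encodes the death ligand TRAIL and was also picked after its values were seen, was higher with PA by at least 1.78 and then at -1.05. Most of the genes higher with PA stayed near their level: for the 166 measured on the control, PA, and PA and ADSC medium arrays, the median difference from control was 1.53 with PA and 1.38 with PA and ADSC medium. Their median difference between the last 2 arrays was -0.29, with quartiles of -0.47 and -0.13. Of the 166, 121 were still at least 2-fold above control, 141 were lower with the medium by any amount (84.9%, 95% Wilson interval 78.7 to 89.6%), 21 by at least 1.5-fold and 4 by at least 2-fold. Among the 17355 genes measured on all 4 arrays, 53.5% were lower by any amount in the same comparison. The 27 interferon genes among the 166 had a median of -0.26 and the other 139 a median of -0.29.

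Both differences contain the PA array, so noise in it alone makes genes that are high with PA look lower afterwards. The simulated unchanged arrays gave a mean of 6.39 genes higher and lower again (2 to 14), against the 4 measured here. With the noise of spots well above background, chosen after these counts were seen, the mean was 0.22 (0 to 2), so the choice of noise decides whether the 4 exceed it. The noise of all replicate spots also draws on spots not well above background, whereas the 4 were well above background on each array concerned. Independent lists of these sizes would share 1.04. Across genes, the PA difference and the following ADSC medium difference had r of -0.459 against a simulated -0.496, and a covariance of -0.054 against a simulated -0.011. When 47 genes were picked as higher with PA on one probe, 41 of them (87.2%) were lower with the medium on a second probe, with a median of -0.28. The 2 probes share the PA array's RNA but not its spots. The count of 10 was 0 with normexp, 4 with genes well above background on both arrays, and 143 without the filter.

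Of 109 genes at least 2-fold lower with PA, 57 were at least 2-fold higher again with the medium, where independent lists would share 1.97. These differences share the PA array as well. Measured on all 3 arrays were 45 of the 57, against a mean of 6.87 (1 to 14) in the simulated unchanged arrays and 3.02 (0 to 7) with the noise of spots well above background. The count of 57 was 5 with normexp and 175 without the filter. Of 15 genes picked as at least 2-fold lower with PA on one probe, 12 were higher with the medium on a second probe, with a median of 0.42, but only 5 were at least 2-fold lower with PA on that second probe, against 39 of the 47 picked as higher. The simulated count, the alternatives and the second-probe count for lower genes were added after the 57 were seen. For the 86 measured on the 3 arrays, the median difference from control was -1.21 with PA and -0.31 with PA and ADSC medium, and 84 were higher with the medium. They include Mmp3, Omd and Mrgprf, which stood within 0.56 of control on the PA and ADSC medium array (-0.39, -0.31 and 0.56), and Ranbp3l, Cck, Slco4a1 and Lrrn3, which stood above it (2.29, 3.48, 2.28 and 1.68). In that order, these genes were also above control with ADSC medium alone, by 1.655, 0.35, 0.60, 1.41, 2.63, 1.26 and 0.81. Most of the 57, but not all, were too. The count of 57 therefore does not separate a reversal of the PA difference from the medium's own difference. Against ADSC medium alone, Mmp3, Omd and Mrgprf differed by -2.05, -0.66 and -0.04 with PA.

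Set against control, the PA and ADSC medium array held 330 genes at least 2-fold higher and 77 at least 2-fold lower, of 18251, and 294 and 59 of these were measured on both arrays, with simulated means of 26.1 and 26.0, and 13 of the 29 lists stood apart. Interferon genes had a median of 1.85 and NF-kB targets of 0.50. Immediate early genes had a median of 0.58, hypoxia and glycolysis genes 0.52, fibrillar collagen and matrix genes 0.18 and cholesterol synthesis genes -0.29. Ccl4 stood at 5.41, Cxcl5 at 3.75, Cxcl1 at 3.10, Il6 at 2.96 and Spp1 at 2.15 above control, and Acta2 at -1.22, Myl9 at -1.25 and Col1a1 at -0.27. The Ccl4 value starts from a low control level of 3.48, and its difference with PA alone was smaller with the normexp background. Normexp gave 148 higher and 10 lower, and no filter 900 and 584.

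**Figure D3:**
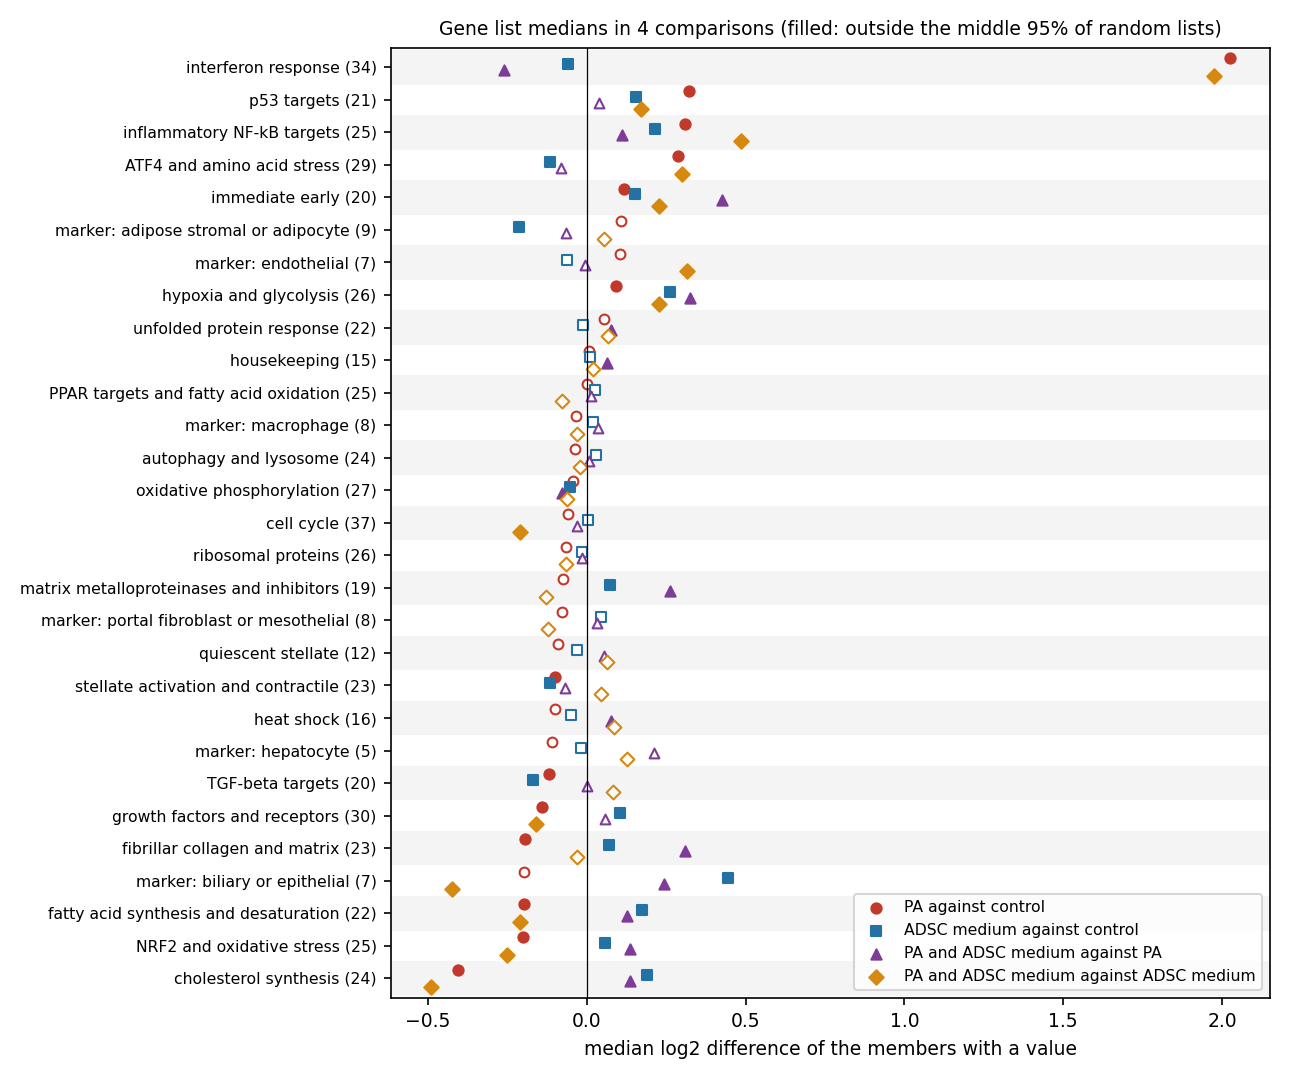
Median log2 difference (horizontal axis) of the members of 29 gene lists in 4 comparisons, 1 symbol per comparison, filled where it lies outside the middle 95% of random lists. The interferon list stands at 2.02 and 1.97 in the comparisons of PA, at -0.06 and -0.26 in those of ADSC medium, and cholesterol synthesis at -0.40 and -0.49 and at 0.19 and 0.14.

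The submitters deposited a pair of probe lists chosen on these arrays, so they are no independent evidence. The list of probes higher with PA than in control held 1580 probes. All were higher here, by a median of 0.58 (0.08 to 4.85), 773 of them by at least 1.5-fold and 292 by at least 2-fold. It held probes of 31 interferon list members, 11 NF-kB targets and 6 ATF4 targets, and of no cholesterol synthesis gene. Of its probes, 43.7% were not well above background on at least 1 of the 2 arrays.

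The list of probes higher with PA than with PA and ADSC medium held 920 probes, all higher with PA here, by a median of 0.77 (0.24 to 2.68). By at least 1.5-fold 871 were higher, by at least 2-fold 221, and 75 of those 221 were well above background on both arrays. Against control, 698 of the 920 were higher with PA, 220 of them by at least 1.5-fold, with a median of 0.27. The list held probes of 5 stellate list members, 3 interferon list members and no NF-kB target. In all, 395 probes were in both lists, where independent lists would share 35.3, and part of that excess may come from the shared PA array. Of the 395, 189 were well above background on the 3 arrays concerned, and 32 were at least 2-fold different in both comparisons.

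Markers of other cell types were examined for signs of other cells, though differences of their medians do not measure the composition of the cultures. Of 14 macrophage markers, Adgre1, C1qa, C1qc, Clec4f, Ptprc and Tyrobp, named after their values were seen, were not well above background on any array. The other 8 were well above background on at least 1 array. Their median was -0.03 with PA against control, 0.02 with ADSC medium against control and 0.04 with PA and ADSC medium against PA, with Cd14 at 1.31 and Lyz2 at -0.88 in the last. With normexp the first and the last of these medians turned to 0.01 and -0.002, and without the filter the second turned to -0.01. Adipose stromal and adipocyte markers, 9 of 15 measured, had a median of 0.11 with PA (0.05 with the 75th percentile scaling), -0.21 with ADSC medium and -0.07 with the medium in the presence of PA, of which the second was -0.06 with the mean of detected probes and the last -0.29 without the filter. Fabp4 was at 0.61 with ADSC medium, and Pparg at -0.46. Biliary and epithelial markers, a list that shares Spp1 with the stellate list, had medians of -0.20, 0.44 and 0.24 (-0.10, 0.23 and 0.10 with normexp), with Sox9 at 0.94 and Krt7 at -0.89 with ADSC medium. Hepatocyte markers, 5 of 13 measured, had medians of -0.11, -0.02 and 0.21, which with normexp were -0.045, 0.006 and 0.06. Endothelial markers had medians of 0.11, -0.06 and -0.006, which with normexp were 0.03, 0.02 and 0.01, and portal fibroblast and mesothelial markers -0.08, 0.04 and 0.03. For PA and ADSC medium against ADSC medium, the endothelial median was 0.32 and the biliary and epithelial median -0.425, and both stood apart. The 15 housekeeping genes had medians of 0.006 with PA, which turned to -0.13 with the 75th percentile scaling, 0.01 with ADSC medium and 0.07 with the medium in the presence of PA. The last stood apart from random lists and was 0.17 with the 75th percentile scaling. Cholesterol synthesis genes had the same median there with that scaling, so a list rise of this size is not told apart from scaling.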

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

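No test was run on the differences in this part, so no test was chosen after a result was seen; each gene stood out because PA went with a level at least 2-fold lower without ADSC medium and at least 2-fold higher with it. Slco4a1, an organic anion transporter gene, differed by -1.41 with PA against control and by 1.02 with PA and ADSC medium against ADSC medium, and this difference between the effects was not tested. Fpr2, a formyl peptide receptor gene, was at -1.16 without the medium and at 1.23 with it, a difference that was not tested. Srpx2 was at -1.24 without the medium and at 1.09 with it, which was not tested either, and its lowest level was 2.31, close to background. The clone-named gene 4921509J17Rik was at -1.39 without the medium and at 1.12 with it, again not tested. Chance alone was not excluded for any of the 4, since each value comes from 1 array.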

How the results depend on the processing

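The alternatives for genes lower with PA and higher again, and the simulation with noise from spots well above background, were chosen only after the counts they check were seen; that simulation lowered the mean number of genes higher with PA and lower again in unchanged arrays from 6.39 to 0.22 (0 to 2), under the 4 measured, because it leaves out the noisiest spots. No paired analysis was run because each group holds 1 array, and for the same reason no array could be left out in turn. With 1 array per group, signal over background sets what can be compared. Genes near a level of 2 to 3 enter with an SD of 0.408 for the difference of 2 spots well above background, or as bounds. Small differences depend most on the processing: 40 of 47 list medians under 0.1 in size turned or moved by over 1.5 times in at least 1 alternative, as did 18 of 39 from 0.1 to 1. All 74 named-gene differences of at least 1 (log2) kept their sign in all alternatives run, as did 112 of 124 smaller ones, 71 of 86 list medians under 1 and the interferon median of 2.02. Neither correlation across genes changed sign, and 37 of 81 alternative values stayed within the limits set for them, among them 87.2% on the second probe.

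With the normexp background, which shrinks dim values together by its construction, the genes higher and lower were 106 and 11 for PA against control, 96 and 4 for PA and ADSC medium against PA, and 19 and 8 for ADSC medium against control. They were 105 and 9 for PA and ADSC medium against ADSC medium and 148 and 10 for PA and ADSC medium against control. With it 0 genes were higher with PA and lower again and 5 lower and higher again, r of the PA difference was 0.644 and r of the ADSC medium difference 0.573. Without the filter, which adds dim probes by its construction, the same counts were 664 and 552, 742 and 479, 623 and 492, 659 and 526, and 900 and 584. The genes higher and lower again were then 143, those lower and higher again 175, and r was 0.294 and 0.252. At 1.5-fold, a lower threshold, the counts were 532 and 596, 985 and 698, 420 and 234, 653 and 579, and 855 and 670, with 145 genes higher and lower again and 257 lower and higher again. With the 75th percentile shift, 60 genes were lower with PA and ADSC medium than with PA and 6 were higher and lower again; the cause was not tested. With genes well above background on both arrays, 4 were higher and lower again, since bounds are left out. With the mean of detected probes, r of the ADSC medium difference was 0.479; the cause was not tested.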

Other observations

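The tests of the interferon and contractile patterns in this part were chosen only after those results were seen, whereas the tests of the deposited list were chosen before. Growth factor genes were mostly lower with PA, 21 of 29 by any amount and only Igfbp6 (-0.66) by at least 1.5-fold, with a median of -0.14 and Igf1 at -0.52. With ADSC medium alone the median was 0.11, with Fgf7, a keratinocyte growth factor, at 0.97, Fgf2 at 0.73 and Igf1 at -0.71. With the medium in the presence of PA, 6 of 29 were at least 1.5-fold higher and none as much lower, among them Fgf7 at 1.26 and Vegfc at 0.67. Immediate early genes had medians of 0.12 with PA (0.07 with the 75th percentile scaling) and 0.15 with ADSC medium alone, with Egr2 at 1.27 in the latter. Hypoxia and glycolysis genes had a median of 0.09 with PA, with Pdk1 at 0.87 and Bnip3 at 0.78. Of 16 heat shock genes, 10 were lower with PA by any amount (median -0.10, or -0.24 with the 75th percentile scaling), and 4 were at least 1.5-fold higher with the medium in the presence of PA, Hspa4l at 1.90 and Hspa1b at 1.57 among them (median 0.08), while the median with ADSC medium alone was -0.05.

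Of 37 cell cycle genes none differed by 1.5-fold with PA against control (median -0.06, Plk1 at -0.46), with ADSC medium (median 0.005) or with both against PA (median -0.03), but the list stood apart with a median of -0.21 for both against ADSC medium and -0.14 for both against control, with 1 and 2 genes lower by at least 1.5-fold. The 27 oxidative phosphorylation genes had medians of -0.04, -0.05 and -0.08 in the same order, with 25 lower by any amount in the second; with the 75th percentile scaling the first was -0.15 and the last -0.025. Ribosomal protein genes had medians of -0.07, -0.01 and -0.02, which with the 75th percentile scaling were -0.29, 0.008 and 0.11. Autophagy and lysosome genes had medians of -0.04, 0.03 and 0.006, and none of the 24 differed by 1.5-fold. Genes of quiescent stellate cells, 12 of 18 measured, had medians of -0.09, -0.03 and 0.06, with Bambi, a decoy receptor for TGF-beta, at 1.45 in the last.

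The interferon genes were higher on both arrays with PA. Array brightness or normalization as the whole source is argued against, since with the 75th percentile scaling the list's median exceeded that of all genes by 1.99 in the PA comparison where the excess was smaller. Macrophages in the PA cultures are argued against as well: the 7 macrophage markers measured on both arrays had a median of -0.032 with PA, and Cd14, Lyz2 and Cd68 among them differed by -0.27, 0.40 and 0.13 at levels of 8.80, 7.88 and 6.66 on the PA array. A carrier, endotoxin or another component of the PA preparation cannot be told apart from PA itself, because 0 labels state what the control received in its place. A response of the cells to PA, the design's own explanation, stays open beside it as untested.

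The contractile genes Acta2, Acta1 and Actc1 were lower on both arrays with ADSC medium, while Actg2 was at -0.36 without PA and -0.07 with it. Cross-hybridization between actin paralogs does not account for 7 contractile genes that are not actins, with medians of -0.52 without PA and -0.64 with it. Of the 7, Tagln, Cnn1 and Myl9 were already among the largest falls without PA, which partly set that median. Tpm1, Tpm2, Cald1 and Lmod1, named after their values were seen, were at -0.36, -0.345, -0.40 and -0.52 without PA. These genes cannot show whether the probes of Acta1 and Actc1 read Acta2, so that question stays open. A fall of all stellate transcripts by about the size of the 2 medians is argued against by the fibrillar collagen list, whose median was 0.072 without PA and 0.31 with it. Without PA the TGF-beta targets (-0.17) and the stellate list (-0.11), which holds contractile genes, stood apart as lower, so a fall that spares the collagens stays open. That ADSC medium goes with lower contractile gene expression is a hypothesis from 1 array per group, found and tested on the same data.

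The deposited list of probes higher with PA than with PA and ADSC medium holds many dim probes. For listed probes well above background on both arrays, a second probe of the same gene had a median difference of 0.57 (95% bootstrap interval 0.50 to 0.63, n = 170, 160 higher with PA) against 0.69 for the listed probes, which argues against noise as their source. For listed probes not well above background on both arrays, only 20 had a second probe to read, with a median of 0.24 (-0.10 to 0.45, 13 higher) against 0.78 for the listed probes. Noise of dim probes cannot be told apart from a real difference there, because the interval covers both predictions. The second probes share the arrays' RNA, so differences between cultures stay open for both parts.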
